A study of Mus musculus with 45 samples.

How the data were processed

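Mouse embryos at E5.25, E5.5 and E5.75 were removed from the decidua, embedded in OCT, frozen and sectioned. Tissue was collected by laser capture microdissection and libraries were made with Smart-seq2, per the labels. The submitters' processing notes name TopHat2 2.0.4, Cufflinks 2.0.2 and genome build mm10, without the role of each tool, the annotation or the normalization step. The deposited tables, 1 per stage, hold FPKM on a log2 scale. The deposited values were read as log2(FPKM + 1), because they start at 0 and the back-transformed values sum to at most 783605 per column, and the unit rests on the table names and these values. Every gene of the E5.25 and E5.75 tables reached an FPKM of 1 in some column. The tables held 10176, 13060 and 13618 genes, of which 8832 were in all. No column of values was left unused.

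At E5.5 the deposited table has 1 log2 value of another kind, a value per section, for each of 7 section numbers whose labels list parts A and B. How the parts were joined is not stated. Of the genes with their highest value in section 2, 208 of 1518 had that value between 0.5 and 1. A mean of a pair filtered at 1 would give such values. For section 7 it was 66 of 1362, near the 65 of 1719 and 73 of 1605 in the separate columns of section 10. A mean of 2 parts is thus not shown for section 7. Parts A and B of section 10 had a column each, named 10 and 11, and were averaged as section 10. The labels conflict here, since the title of the second gives part B of section 10 and its source name gives section 11. Taken as sections 10 and 11, 2889 genes passed at E5.5, against 2547. Because the other parts had joined values only, the comparison of part A with part B could not be run.

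Genes with an FPKM of at least 1 in at least 2 of the samples fitted were tested with limma 3.58.1 (R 4.3.3), eBayes with trend, 2-sided, with Benjamini-Hochberg adjustment at 0.05. Each stage was fitted alone as a line in section number, rescaled to 0 at the lowest and 1 at the highest number, so a change is the fitted difference on the log2 scale from first to last section and its error is the standard error. There were 7, 9 and 17 section numbers, with VE libraries left out. VE was compared with the other libraries of sections 6 and 7, 2 against 2, without a block. The shared numbers are positions, and the correlation of the section 6 samples' deviations from their group means across genes was 0.000773; with only 2 pairs this does not settle whether the samples pair, and the fit with a section block is among the alternatives. As far as the labels say, each stage is 1 embryo.

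The 22 marker lists were fixed before the data were examined. Lists with at least 3 members were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation and fry beside it, and with Benjamini-Hochberg adjustment over the lists of a comparison. Camera compares a list with all other genes; fry asks whether its members move one way and does not compare them with other genes. The lists cover epiblast, naive pluripotency, formative and primed pluripotency, extraembryonic ectoderm, ectoplacental cone and trophoblast, visceral endoderm, distal and anterior visceral endoderm, parietal endoderm, primitive streak, the Nodal, BMP and FGF pathways, epithelial polarity, basement membrane, cell cycle, glycolysis, cholesterol synthesis, ribosomal proteins, mitochondrially encoded genes, stress genes, decidua, and blood and leukocytes. Some genes are in more than 1 list. Slopes of list means were compared between stages by a permutation test of residuals (2-sided, 100000 resamples, Benjamini-Hochberg over 55 comparisons).

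Genes were named by a rule set before the data were examined: the 10 with the largest rise and the 10 with the largest fall among genes past the threshold with a mean FPKM of at least 5, leaving out unnamed gene models, and up to 4 members of each list with the smallest p. Alternatives were pseudocounts of 0.1 and 5, no filter or a filter at 5, rescaling to a common sum, quantile normalization, eBayes without trend or robust, detected genes as a covariate, a spline, other choices of sections, and leaving out each section. The fits were tested on simulated data with known changes of 2, 4 and 8. Of these, 0%, 2.99% and 72.7% were recovered at E5.25, 0%, 55.2% and 98.5% at E5.5, 25.4%, 73.1% and 100% at E5.75, and 0%, 0% and 1.59% in the VE comparison. Changed genes had a mean log2 value above 4, and noise was drawn independently for each gene, without a shared loss of detection. The rates therefore say little about genes listed at 0 in a whole group. The tables hold no counts, so sequencing depth and its precision are unknown. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.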

Results

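The study examined how gene expression differs along the proximal-distal axis of mouse embryos shortly after implantation, at embryonic days E5.25, E5.5 and E5.75. At these stages the embryo is a small cup in which the epiblast, the source of the embryo proper, is joined to the extraembryonic ectoderm and the ectoplacental cone, which give rise to the placenta. A layer of visceral endoderm covers both. Frozen embryos were cut into numbered sections, tissue was collected by laser capture microdissection, and RNA from each piece was sequenced with Smart-seq2, a full-length protocol for very small RNA amounts. The labels describe 45 samples. There were 7 from E5.25, 17 from E5.5 and 21 from E5.75, the last including 2 marked VE, the usual abbreviation of visceral endoderm, from sections 6 and 7. The tables analysed here held 7 sections at E5.25, 9 section numbers at E5.5 and 17 sections plus both VE libraries at E5.75; sections 9 and 13 of E5.75 were not analysed here. As far as the labels say, the sections of a stage came from 1 embryo, so p-values compare sections and not embryos, and are too small as statements about embryos. The labels do not say at which end of the axis section 1 lies, so directions are given in section number.

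Low-numbered sections yielded fewer genes. At E5.25, 2607, 3374, 4282 and 2046 genes reached an FPKM of 1 in sections 1, 2, 3 and 4, against 5636 to 6461 in sections 6 to 8. At E5.5, detection was 2288 genes in section 1, 4019 in section 2 and 5950 to 6467 in the columns from section 6 on. At E5.75 it was 3211 and 3424 genes in sections 1 and 2, 5303 to 8217 in the others, and 1496 and 2147 in the VE libraries of sections 6 and 7. Rn45s, the precursor of ribosomal RNA, took 69.8% of the summed FPKM in section 1 of E5.5, 52.8% in section 1 of E5.75, and 62.2% and 48.8% in the VE libraries, against 2.88% in section 19 of E5.75. Gapdh, a glycolytic enzyme made by nearly every cell, was listed at 0 in section 1 of E5.5. A value of 0 is therefore given only as a listing of 0. Sequencing depth is unknown, because the tables hold no counts.

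**Figure D1:**
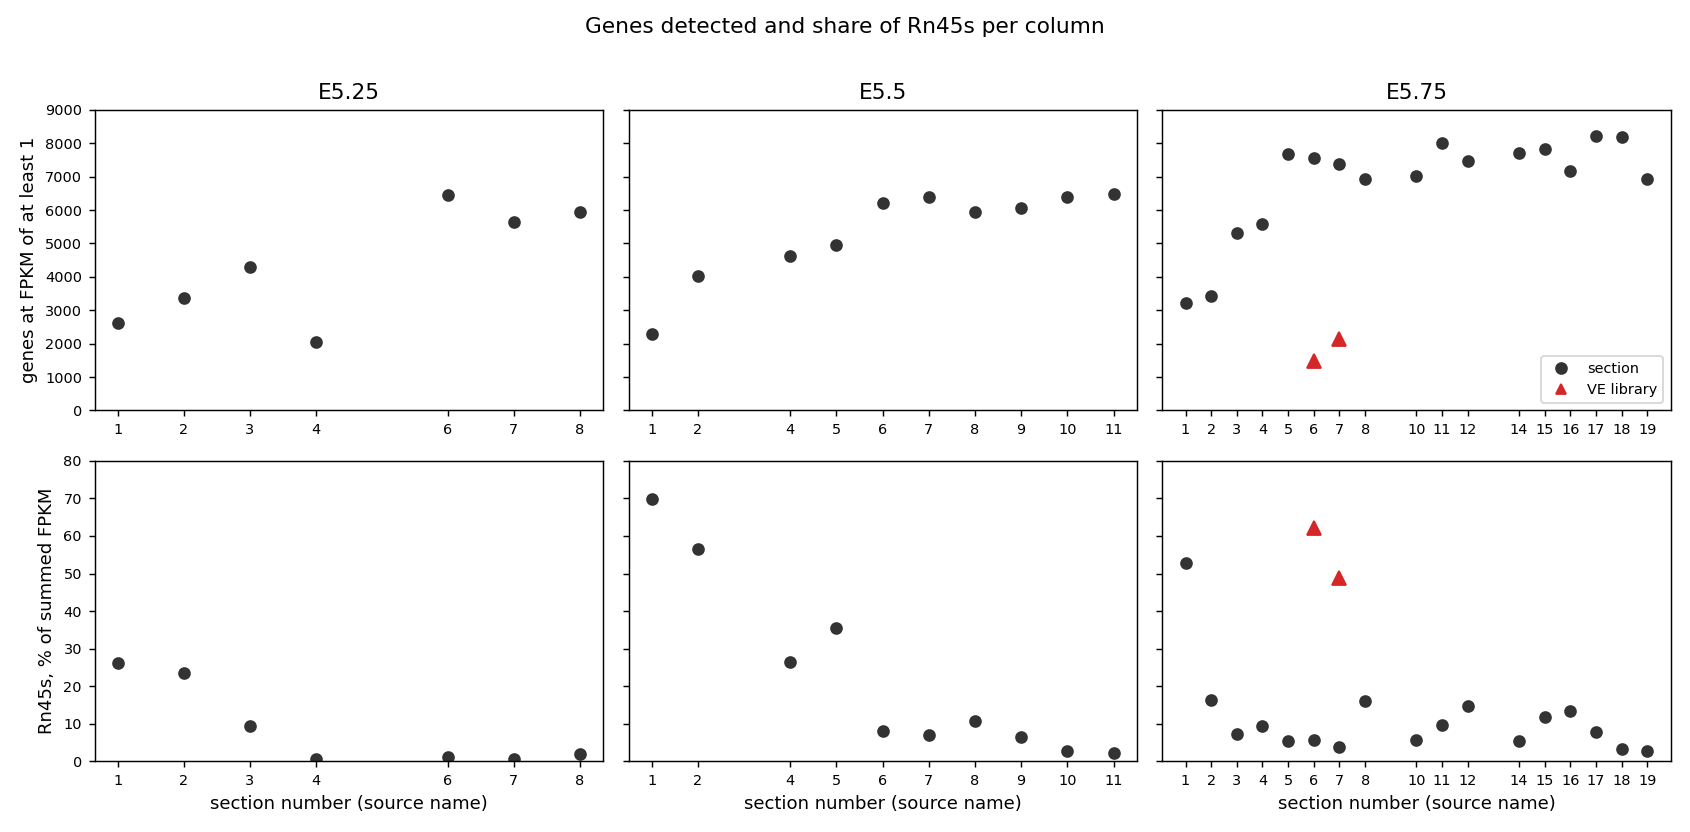
Number of genes with an FPKM of at least 1 (upper row) and percent of the summed FPKM taken by Rn45s (lower row) against section number for each stage; each point is 1 column of the tables, triangles are the VE libraries, and at E5.5 the numbers 10 and 11 are parts A and B of section 10. Among the E5.75 columns fewest genes were detected in the VE libraries, with 1496 and 2147, and Rn45s was highest in section 1 of E5.5 at 69.8%.

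At E5.75 the first question was which genes changed from low to high section number. Most genes of the epiblast list and of the list for formative and primed pluripotency fell. Pou5f1 (Oct4), a transcription factor of pluripotent cells, stood between 6.17 and 7.53 on the log2(FPKM + 1) scale in sections 2 to 8 and at 3.70 in section 10, and from there on at 2.66 in section 12, 1.37 in section 15 and 0 elsewhere. Its fitted fall from the first to the last section was -7.16 ± 1.54 (log2, SE, n = 17 sections, adjusted p = 0.00247, limma with Benjamini-Hochberg adjustment). In section 1, where few genes were detected, it was listed at 0. Pou5f1 lies on chromosome 17 from 35506018 to 35510772 (mm10). Pim2, a serine/threonine kinase, fell by 8.15 ± 1.06 and Sox4, a transcription factor, by 6.55 ± 0.84. Otx2, a transcription factor of the epiblast and anterior visceral endoderm, fell by 5.38 ± 1.02 and was listed at 0 from section 10 on. Of 15 measured members of the epiblast list, 11 fell and 4 did not pass, and 12 passed when adjusted over the list alone (median change -3.28). Of 12 members of the list for formative and primed pluripotency, the states of the epiblast after implantation, 10 fell, 10 adjusted over the list alone (median -2.98). Among these were the DNA methyltransferase Dnmt3b (-4.02 ± 0.73) and the transcription factor Pou3f1 (-3.62 ± 0.88). Both lists fell against all other genes in the camera test (adjusted p = 1.79e-16 and 5.36e-16), also with an estimated correlation (adjusted p = 0.0287 and 0.00686). Further large falls were those of Mtap7d3 (-7.24 ± 0.85), Igfbp2, which binds insulin-like growth factors (-6.85 ± 1.18), Tcea3 (-6.61 ± 0.89), Bcat2, an aminotransferase of branched-chain amino acids (-6.49 ± 0.90), Zcwpw1 (-5.25 ± 0.70) and Mdk, a secreted growth factor (-5.25 ± 1.40).

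Genes of the trophoblast lineage rose in the opposite direction. Phlda2, an imprinted gene that limits placental growth, rose by 10.13 ± 0.77 (adjusted p = 2.14e-08, limma with Benjamini-Hochberg adjustment, n = 17), and was listed at 0 in sections 1 to 3 and stood at 9.58 to 10.12 in sections 17 to 19. Phlda2 lies on chromosome 7 from 143501545 to 143503150 (mm10). Tfap2c, a trophoblast transcription factor, rose by 9.40 ± 0.85 and was at or below 1.26 up to section 8 and at or above 5.83 from section 10 on. Hand1, a transcription factor of trophoblast giant cells, rose by 8.38 ± 0.92, and Gata3 by 5.81 ± 0.66. Of 14 measured members of the ectoplacental cone and trophoblast list, 11 rose and 3 did not pass, with 12 passing adjusted over the list alone (median change 5.10). Its camera test gave an adjusted p of 2.78e-09, and 0.00686 with an estimated correlation. Of 16 members of the extraembryonic ectoderm list, 10 rose, 10 adjusted over the list alone (median 3.13). They included Elf5, a trophoblast stem cell transcription factor (6.86 ± 0.87), the Wnt ligand Wnt7b (5.85 ± 0.92) and the FGF receptor Fgfr2 (5.51 ± 0.85). That list passed camera at the preset correlation (adjusted p = 0.000119) and did not with an estimated correlation (adjusted p = 0.312). Further large rises were those of Fabp3, a fatty acid binding protein (10.16 ± 1.05), the lectin Lgals1 (9.05 ± 0.84), S100a6 (8.65 ± 1.12), Rhox5 (8.54 ± 1.47), the growth factor Igf2 (8.35 ± 0.92), the creatine kinase Ckb (8.01 ± 0.77) and the syndecan Sdc4 (7.97 ± 0.71).

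**Figure D2:**
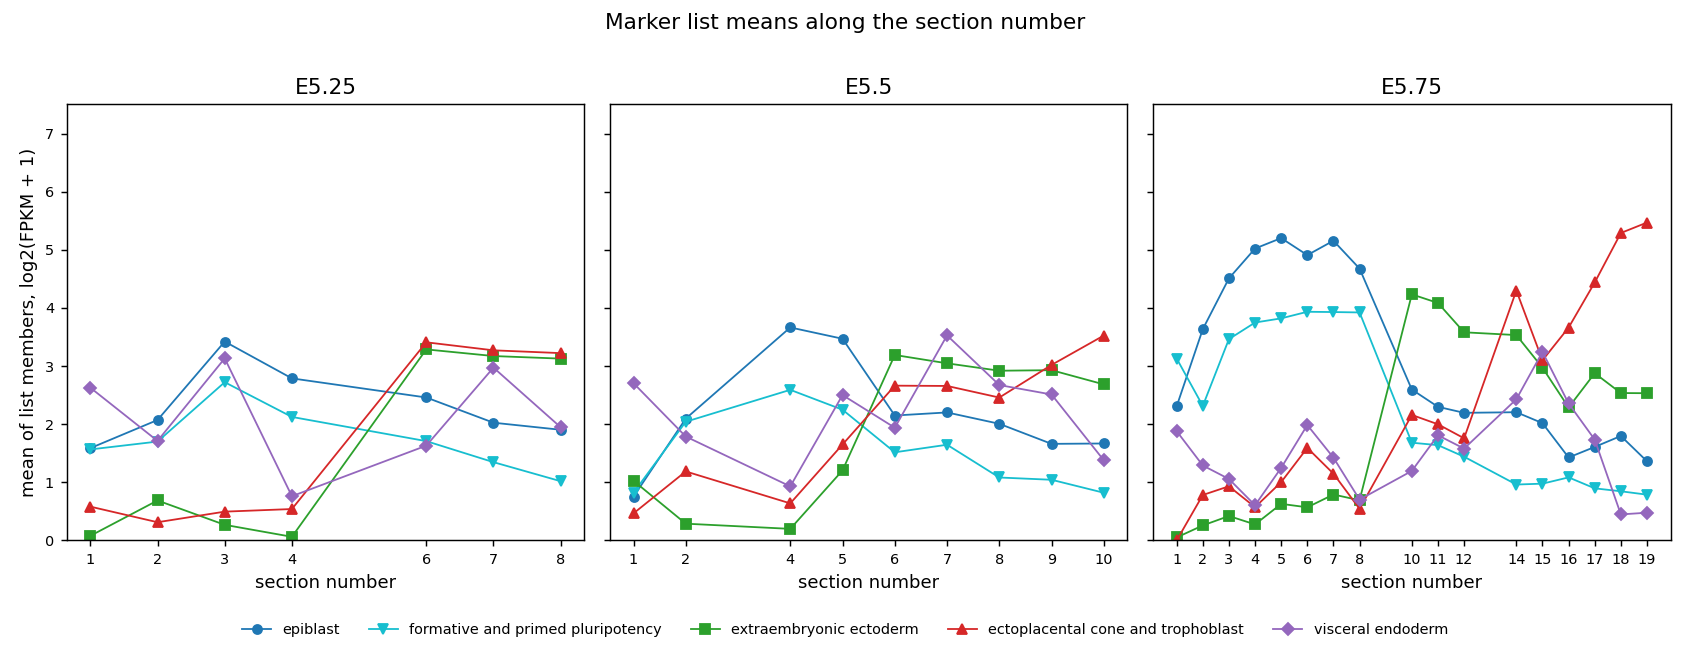
Mean log2(FPKM + 1) of the tested members of 5 marker lists in each section, 1 panel per stage, against section number. Each point is the mean over list members in 1 section. Levels are not compared between stages, because the normalization step is not stated. At E5.75 the epiblast list had a median change of -3.28 and the ectoplacental cone and trophoblast list one of 5.10 from the first to the last section.

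In all, 2339 of 11149 genes tested at E5.75 passed, 2108 rising and 231 falling, and the median change of all tested genes was 0.80. With the number of detected genes as a covariate 624 genes passed, 405 rising and 219 falling, and 472 of them were among the 2339. With quantile normalization 1341 passed, 842 rising and 499 falling. Of the 8 lists that passed camera, primitive streak was lost with quantile normalization (adjusted p = 0.0662) and with detected genes as a covariate (adjusted p = 0.133), and cholesterol synthesis with that covariate (adjusted p = 0.768). Without sections 1 and 2, the sections of low detection, 1407 passed, 1033 rising and 374 falling.

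Some signalling genes also changed along the E5.75 sections, but none of the 4 lists given here passed camera with an estimated correlation. For comparison, 2339 of 11149 genes passed over all. Of 11 FGF pathway genes, 4 fell and 2 rose (6 adjusted over the list alone), among them the ligand Fgf4 (-4.32 ± 0.94), the feedback phosphatase Dusp6 (-3.35 ± 0.73) and the early response gene Fos, which rose by 5.21 ± 0.89. The list's median change was -1.65 and its camera test passed (adjusted p = 0.000426), but not with an estimated correlation (adjusted p = 0.103). In the Nodal list, the ligand Nodal fell by 2.64 ± 0.86 and its co-receptor Tdgf1 by 4.87 ± 1.22, while 2 of the 9 members rose and 5 did not pass (4 passed adjusted over the list alone, camera adjusted p = 0.0528). The Nodal call was lost in 7 of 30 alternatives, among them those without section 1 (-1.83, adjusted p = 0.128), section 3 (adjusted p = 0.0623) or section 18 (adjusted p = 0.0508). The primitive streak list had 7 members, of which Fgf8 fell (-2.51 ± 0.67), Nodal fell as above, with the same losses, Eomes rose by 4.09 ± 1.05, and 3 passed adjusted over the list alone; its camera test passed (adjusted p = 0.0212), but not with an estimated correlation (adjusted p = 0.0901). Of 12 BMP pathway genes, the BMP target Id2 (7.37 ± 1.26) and the ligand Bmp8b (2.72 ± 0.73) rose (3 adjusted over the list alone, camera adjusted p = 0.483).

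In the list of the distal and anterior visceral endoderm, the signalling centre at the distal tip, 3 of 8 members fell at E5.75 and 1 rose, with 5 passing adjusted over the list alone. The transcription factor Lhx1 was highest in section 1 and fell by 2.41 ± 0.83 (adjusted p = 0.0397), and the Wnt receptor Fzd5 fell by 1.82 ± 0.63, while the semaphorin receptor Nrp2 rose by 1.90. The Lhx1 call was lost in 12 of 28 alternatives and the Fzd5 call in 15 of 29 (adjusted p up to 0.918 for each). Without section 1 their changes were -1.03 (adjusted p = 0.141) and -1.10 (adjusted p = 0.164), and neither passed without section 2, 14, 16, 17 or 18, nor Lhx1 without section 15 (adjusted p = 0.0507 to 0.118). The list's median change was 0.12, its mean was -0.59, and its camera direction was down (adjusted p = 0.0528). Of 24 visceral endoderm genes only Cited1 rose (3.46 ± 1.11), none passed over the list alone, and the median change of 0.42 lay below that of all genes (camera adjusted p = 0.137). The Cited1 call was lost in 12 of 30 alternatives, among them those without section 1, 2, 3, 4, 15, 16 or 17 (adjusted p = 0.0518 to 0.0708). Amn, the endocytic co-receptor of that tissue, did not pass and was highest in section 15 at 5.39 and listed at 0 in sections 18 and 19; it rose without section 18 (3.49, adjusted p = 0.0417) or section 19 (3.70, adjusted p = 0.0264). Some genes of the maternal decidua list rose toward the high-numbered sections, as the trophoblast genes did. Of 8, Cryab (5.69 ± 1.02), Prl8a2, Htra1 (3.55 ± 0.71) and Cebpb (2.57 ± 0.54) rose and 4 did not pass, among them Dcn (-0.81 ± 0.53). Adjusted over the list alone 5 passed, and the list did not pass camera (adjusted p = 0.0898). Prl8a2 was at 7.46 in section 19 and 6.17 in section 14, and did not pass without section 19 (3.61, adjusted p = 0.058). Of the blood and leukocyte list 2 members could be tested, too few for a list test, and Cd52 rose by 3.51 ± 0.78.

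Of 7 stress and immediate early genes 5 rose at E5.75, 5 adjusted over the list alone, with Gadd45b (5.24 ± 0.75), Junb (4.20 ± 0.74) and Fos among them (camera adjusted p = 0.0212, and adjusted p = 0.103 with an estimated correlation). In the cholesterol synthesis list 7 of 12 rose, 8 adjusted over the list alone, among them Fdps (4.41 ± 0.90). This list passed camera (adjusted p = 0.0257), but not with an estimated correlation (adjusted p = 0.489). In the list for epithelial polarity and lumen formation 3 of 14 rose (3 over the list alone), with the tight junction gene Cldn4 (7.60 ± 0.77) and the membrane linker Ezr (3.25 ± 0.60) among them, and the list did not pass (adjusted p = 0.1997). Of 9 genes of naive pluripotency, Zfp42 (5.40 ± 0.82), Klf5 (3.15 ± 0.74) and 1 other rose and 6 did not pass (5 passed over the list alone), and the list did not pass camera (adjusted p = 0.0898). Parietal endoderm had 4 of 13 rising with Snai1 among them (4.62 ± 0.64; 4 over the list alone, camera adjusted p = 0.4597). Basement membrane had 3 of 12 rising and 1 falling (4 over the list alone, adjusted p = 0.271), with Nid1 rising by 3.18 ± 0.55 and Nid2 falling by 2.21 ± 0.79. The Nid2 call was lost in 19 of 29 alternatives. It held without section 1, 3 or 15 and was lost without any other single section (adjusted p = 0.0541 to 0.157), with -1.28 without section 2. Glycolysis had 2 of 13 rising with the glucose transporter Slc2a1 among them (3.67 ± 0.84; 2 over the list alone, adjusted p = 0.483). Among cell cycle genes 4 of 16 rose (4 over the list alone, adjusted p = 0.137), and 4 of 15 ribosomal protein genes rose (6 over the list alone, adjusted p = 0.154). Camera compares a list with all other genes, so that its direction was down for the visceral endoderm and basement membrane lists although their medians were above 0.

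At E5.5 some trophoblast genes rose as well. Phlda2 went from a listing of 0 in sections 1 and 2 to 7.96 in section 10, a rise of 8.15 ± 1.01 (adjusted p = 0.000449, limma with Benjamini-Hochberg adjustment, n = 9 section numbers). The keratin gene Krt7 rose by 5.47 ± 0.84, Hand1 by 5.30 ± 0.95 and Tfap2c by 5.41 ± 0.89. Of 13 genes of the ectoplacental cone and trophoblast list 6 rose and 7 did not pass, 6 passing adjusted over the list alone, and of 16 extraembryonic ectoderm genes 9 rose and 7 did not pass, 12 passing adjusted over the list alone, including Bmp8b (4.31 ± 0.95) and Fgfr2 (3.25 ± 0.72). At the other end, Lhx1, at 7.32 in section 1 and 4.32 in section 2, fell by 6.28 ± 1.19 (adjusted p = 0.00187), and Fzd5 fell by 2.32 ± 0.63. These were the 2 of 5 members of the distal and anterior visceral endoderm list that passed (2 over the list alone). In the visceral endoderm list of 23, Apob fell by 3.74 ± 0.80, while Apoe (6.05 ± 1.28) and Cited1 (4.83 ± 1.18) rose and 20 did not pass (3 passed over the list alone, median change 0.0017). Sox4 fell by 3.48 ± 0.90, the 1 of 9 primed pluripotency genes to pass over all genes or over the list alone (median -1.11), and the epiblast list of 13 had 1 rise and 0 falls, 0 over the list alone, with a median of -0.68. Neither Dnmt3b (-2.31 ± 0.91, adjusted p = 0.063) nor Tdgf1 (-1.98 ± 1.07, adjusted p = 0.158) passed. Tdgf1 passed without section 1 (-3.96, adjusted p = 0.0143) and Dnmt3b without section 2 (-2.87, adjusted p = 0.039). Section 1 also held Hba-a1Hba-a2, the joined alpha globin genes, at 8.60, which fell by 6.15 ± 1.37, and Hoxa10, a decidual transcription factor, at 5.08, which fell by 3.28 ± 1.04.

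Genes that most cells use rose at E5.5 too. Of 16 ribosomal protein genes 11 rose (13 over the list alone, median change 3.57), of 12 glycolysis genes 7 (7, median 3.26), of 16 cell cycle genes 12 (12, median 3.43) and of 12 cholesterol synthesis genes 9 (11, median 2.67). Examples were Ldha (6.45 ± 1.34) and Pcna (6.16 ± 1.23). The largest rises included Usmg5 (10.23 ± 1.52), Rps27l (9.71 ± 1.31), Lgals1 (9.08 ± 1.25), Fabp3, the respiratory chain subunit Cox6b1 (8.89 ± 1.22), Cd63 (8.88 ± 1.11) and Id2 (8.30 ± 1.18). Beside Lhx1 the largest falls included Vmn2r112 (-6.99 ± 1.29), Rb1 (-6.83 ± 2.19), Lars2 (-5.75 ± 0.68), Fut8 (-5.73 ± 0.88) and Zfp488 (-5.73 ± 0.94), all highest in section 1. Without section 1 Rb1 did not pass (-1.41, adjusted p = 0.469).

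Camera passed 10 of 20 lists at E5.5. Upward were the cell cycle, ribosomal protein, extraembryonic ectoderm, cholesterol synthesis, ectoplacental cone and glycolysis lists (adjusted p = 0.00471 to 0.0456), and downward were the primed pluripotency, epiblast, distal and anterior visceral endoderm and visceral endoderm lists (adjusted p = 0.00471 to 0.0167). None passed with an estimated correlation (adjusted p = 0.52 to 0.546). With quantile normalization 4 passed upward and 1 downward, and the lists lost were cholesterol synthesis, epiblast and distal and anterior visceral endoderm (adjusted p = 0.0598 each) and glycolysis and visceral endoderm (0.0611 each). With detected genes as a covariate only the primed pluripotency and epiblast lists of the 10 passed, and parietal endoderm passed upward (adjusted p = 0.0161). The lists for blood and leukocytes (1 of 4 rose, 1 fell, 2 over the list alone, adjusted p = 0.0557), BMP (3 of 10 rose, 3, 0.428), FGF (4 of 10 rose, 4, 0.629), Nodal (1 of 4 rose, 1, 0.254), naive pluripotency (Zfp42, 1 of 5 rose, 2, 0.623), epithelial polarity (Cdh1, Epcam and 3 others of 14 rose, 5, 0.412), parietal endoderm (Sparc, Srgn and 2 others of 10 rose, 4, 0.629), basement membrane (1 of 9 rose, 1, 0.428), decidua (Cryab and Htra1 rose and Hoxa10 fell among 6, 3, 0.365) and stress genes (3 of 6 rose, 3, 0.412) did not pass, the figures after each count being the passing members adjusted over the list alone and the camera adjusted p. The medians of the FGF, basement membrane and decidua lists were above 0 while their camera direction was down, and the Nodal list had a median of -0.37 and a mean of 0.06.

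Of 8251 genes tested at E5.5, 2547 passed, 2332 rising and 215 falling, around a median change of 1.22 over all tested genes. With the number of detected genes as a covariate 0 genes passed in limma, 411 had an unadjusted p under 0.05, and Lhx1, Apoe, Rb1, Hoxa10, Epcam, Gapdh and Ldha changed sign. With quantile normalization 1179 passed, 850 rising and 329 falling, and without section 1, the section of low detection, 1703 passed, 1565 rising and 138 falling.

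At E5.25 few genes passed. Pou5f1 was at 6.71, 5.65 and 5.49 in sections 2, 3 and 4, at 2.20 in section 6 and listed at 0 in sections 1, 7 and 8. Its fitted change of -3.90 ± 2.11 (n = 7 sections) did not pass (adjusted p = 0.186, limma with Benjamini-Hochberg adjustment), but without section 1 it was -8.68 (adjusted p = 0.0399). Tdgf1 was at 4.87 and 4.97 in sections 3 and 4, at 1.43 in section 6 and listed at 0 in the others, and its change did not pass (-1.15 ± 1.80). Other members of the epiblast list had positive fitted changes that did not pass, such as Utf1 (4.46 ± 1.63, adjusted p = 0.0738) and Pou3f1 (3.34 ± 1.79, adjusted p = 0.183). Pou3f1 was at -0.28 without sections 1, 2 and 4 and at -1.37 with detected genes as a covariate. The ligand Bmp4 was listed at 0 in sections 1 to 4 and stood at 4.98, 5.26 and 4.74 in sections 6, 7 and 8 (adjusted p = 0.0543), and Elf5 at 4.23, 4.49 and 4.11 (adjusted p = 0.0549). Both passed without section 2, 3 or 4 (adjusted p = 0.0268 to 0.0488). Genes that passed included Phlda2 (8.13 ± 1.73, adjusted p = 0.0442), Fabp3 (9.65 ± 1.84), Ly6a, Lgals1 (8.67 ± 1.78) and Id2 (8.50 ± 1.73). Also rising were Tomm5 (8.82 ± 1.85), Uqcr11 (8.75 ± 1.87) and Cox8a (8.42 ± 1.80), which encode mitochondrial proteins. None of these rising genes passed without section 6 (adjusted p = 0.0552 to 0.0625). The falling genes that passed were Rn45s (-5.40 ± 0.91) and Lars2 (-7.43 ± 1.62). In all 29 of 7148 genes passed, 27 rising, around a median change of 1.45 over all genes; 36 passed without the low-detection sections 1, 2 and 4, and 16 of them were among the 29. With the number of detected genes as a covariate 0 passed in limma, with 599 at an unadjusted p under 0.05, and leaving out section 6 or section 4 gave 3 or 818 genes.

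Of the lists at E5.25, extraembryonic ectoderm (median change 3.64, adjusted p = 0.00157) and cholesterol synthesis (3.94, 0.0172) passed camera upward, and the primed pluripotency (-1.07, 0.0172), epiblast (-0.22, 0.0223) and visceral endoderm (-0.31, 0.0172) lists downward. None passed with an estimated correlation (adjusted p = 0.59 to 0.602). With quantile normalization 4 lists passed upward and 1 downward: the primed pluripotency (adjusted p = 0.0597) and epiblast (0.105) lists were lost, and the trophoblast (0.0345) and ribosomal protein (0.0419) lists passed upward. With detected genes as a covariate cholesterol synthesis, ribosomal proteins and, downward, visceral endoderm passed, and extraembryonic ectoderm (adjusted p = 0.0735), primed pluripotency (0.289) and epiblast (0.696) did not. Over all genes 0 of the 15, 12, 9, 13 and 17 members of these lists passed, and over the list alone 12, 9, 0, 0 and 0. In the trophoblast list 1 of 9 members rose (7 over the list alone) and in the BMP list 1 of 9 (4). In no other list did a member pass over all genes. Over the list alone 3 cell cycle, 3 FGF, 3 stress, 4 glycolysis, 4 ribosomal protein and 1 Nodal gene passed, and 0 in the lists for epithelial polarity, naive pluripotency, parietal endoderm, basement membrane and distal and anterior visceral endoderm. The camera adjusted p of the lists that did not pass lay between 0.057 and 0.734. The basement membrane list had a median of -0.36 and a mean of 0.86, and the parietal endoderm list a median of 0.14 with a downward camera direction. The lists for primitive streak, decidua, and blood and leukocytes had too few members to test at E5.25, as had primitive streak at E5.5.

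Across stages, 1005 genes rose at both E5.5 and E5.75 and 23 fell at both, where independent lists of these sizes would share 554 and 3.49. Rising at all 3 stages were 17 genes, among them Fabp3, Lgals1, Id2, Ly6a, Phlda2, Tomm5 and Cox8a. Lhx1, Fzd5, Sox4 and Fut8 were among those that fell at both later stages. Between E5.25 and E5.5, 25 rises and 2 falls were shared (9.29 and 0.0401 for independent lists), and between E5.25 and E5.75, 19 rises and 0 falls (6.61 and 0.0425). These overlaps have no test, and the stages share the lower detection in low-numbered sections. The slope of a list mean from first to last section differed between stages for 2 of 55 comparisons by a permutation test with 100000 resamples. The glycolysis list had a slope of 3.46 at E5.5 over 12 members and 1.22 at E5.75 over 13 (permutation p = 0.00174, adjusted p = 0.0479). Section 1 of E5.5, where few genes were detected and Gapdh was listed at 0, enters that slope. The test was not repeated without it, so a difference in detection between these embryos is not set apart. The Nodal list had a slope of 1.41 at E5.25 over 5 members and -0.55 at E5.75 over 9 (permutation p = 0.00169, adjusted p = 0.0479). Relative to the mean of all tested genes the Nodal difference did not pass (permutation p = 0.0117, adjusted p = 0.115). The epiblast list had slopes of -0.08 and -3.33 at E5.5 and E5.75, a difference that did not pass (permutation p = 0.0166, adjusted p = 0.101).

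The VE samples were compared with the other samples of sections 6 and 7 at E5.75. Among genes of visceral endoderm, which takes up and carries lipids, 3 apolipoprotein genes were higher in the VE libraries. The apolipoprotein gene Apom stood at 8.48 and 9.50 in the VE libraries of sections 6 and 7 against 4.13 and 2.84 in the other libraries, Apoe at 7.99 and 9.22 against 4.11 and 4.70, and Apob at 3.55 and 5.53 against 0.52 and 0.43. The lysosomal protease Ctsb stood at 7.25 and 7.57 against 2.05 and 1.44, Glrx at 5.87 and 7.06 against 1.64 and 0.22, and Lrpap1, a chaperone of lipoprotein receptors, at 6.11 and 5.08 against 1.17 and 0.93. Each passed, with differences from 4.07 ± 0.87 for Apob to 5.66 ± 0.78 for Ctsb (log2, SE, n = 2 against 2, adjusted p = 0.0124 to 0.0337, limma with Benjamini-Hochberg adjustment). The adjustment depends on all genes tested, of which 3996 of 6413 had an unadjusted limma p under 0.05, most of them lower in VE. With so many, an unadjusted limma p of 0.00473 for Ctsb or 0.00894 for Glrx was enough to pass. S100a13, listed at 0 in both other libraries, was at 4.54 and 7.13, and Ckap4 at 5.62 and 7.81 with lower values in both other libraries. Of 15 visceral endoderm genes 3 were higher, Cited1 was lower and 11 did not pass (1 over the list alone), with a median difference of 2.42. The list passed camera (adjusted p = 1.05e-09), but not with an estimated correlation (adjusted p = 0.396). Only 15 of its 28 members were tested. Genes below an FPKM of 1 in both other libraries entered only if they reached 1 in both VE libraries, so the filter itself favours an upward camera result.

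**Figure D3:**
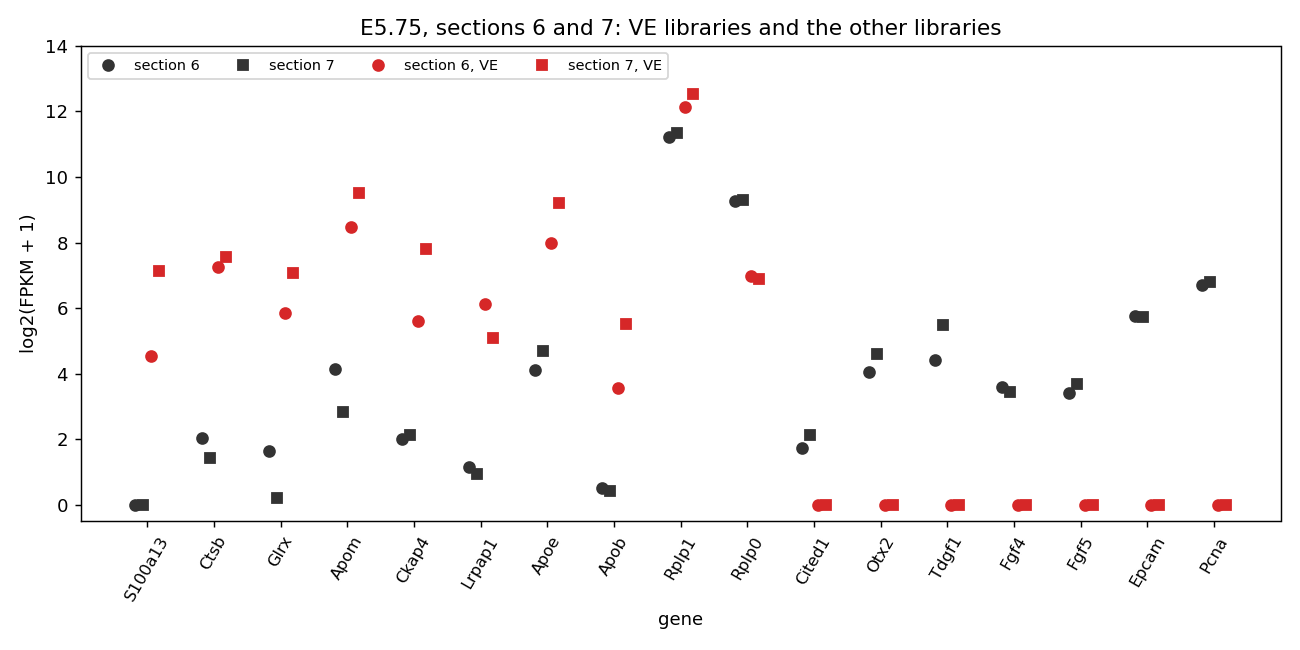
Values in log2(FPKM + 1) of 17 genes in the 4 E5.75 libraries of sections 6 and 7; black marks are the other libraries and red marks the VE libraries, circles section 6 and squares section 7. Apom reached 8.48 and 9.50 in the VE libraries, and Otx2, Tdgf1, Fgf4, Fgf5, Epcam and Pcna were listed at 0 in both.

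Several epiblast genes found in sections 6 and 7 were listed at 0 in both VE libraries, among them Otx2, Tdgf1, Fgf4, Fgf5 and Slc7a3, and so were genes of cell division and adhesion such as Pcna, Cdk1 and Epcam. This was not particular to epiblast genes: 5 of the 14 on that list passed lower, and the list did not pass camera (adjusted p = 0.999). Of 6413 genes tested, 3671 passed, 40 higher and 3631 lower in VE. Of those lower, 3270 were listed at 0 in both VE libraries, so that their spread there was 0, and 361 had a value in a VE library. The 40 higher had values in both. With the number of detected genes as a covariate 1053 passed, 638 higher and 415 lower. Pou5f1, chosen after its values were seen, was listed at 0 in the VE library of section 6 and at 6.73 in that of section 7. With quantile normalization 0 genes passed in limma, with 3090 at an unadjusted p under 0.05. Leaving out the other library of section 6, or that of section 7, left differences of similar size in the apolipoprotein and other genes named above as higher. Apom differed by 6.15 and 4.86, Apoe by 3.90 and 4.50, Apob by 4.11 and 4.02 and Ctsb by 5.97 and 5.36. With 1 library left in that group, the calls of all these genes were lost. Of these calls Ckap4 was lost in 10 of 16 alternatives, Apob in 7 of 14, Apom, Apoe and Glrx in 6 of 16 each, Ctsb in 5 of 16, S100a13 in 5 of 14 and Lrpap1 in 4 of 16, with 1 reversal. Without the VE library of section 6, 711 were higher and 4612 lower, and without that of section 7, 555 were higher and 5069 lower.

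Other lists in the VE comparison were as follows. Members passing lower were 5 of 14 epiblast genes (5 over the list alone, camera adjusted p = 0.999), 5 of 12 primed pluripotency genes (5, 0.999), 5 of 9 FGF genes (5, 0.999), 3 of 6 BMP genes (3, 0.999), 3 of 6 Nodal genes (2, 0.618), 10 of 16 cell cycle genes (10, 0.605), 10 of 12 cholesterol synthesis genes (10, 0.177), 5 of 13 glycolysis genes (4, 0.999), 4 of 13 epithelial polarity genes (4, 0.5898), 1 of 3 trophoblast genes (1, 0.398) and 1 of 3 distal and anterior visceral endoderm genes (1, 0.177). Camera placed 5 further lists above the other genes, whose median difference was -2.09, and none of these did so with an estimated correlation (adjusted p = 0.346 to 0.63). They were parietal endoderm (0 of 6 passing, median 2.51, adjusted p = 4.12e-06), ribosomal proteins (2 of 15 higher and 1 lower, median -0.41, 3.93e-05), primitive streak (0 of 5, mean 0.69, 0.00153), extraembryonic ectoderm (0 of 4, median 0.77, 0.00657) and basement membrane (3 of 8 lower, median 0.59, 0.0283). With quantile normalization ribosomal proteins did not pass (adjusted p = 0.304). Over the list alone 2 basement membrane members passed and 0 of the other 4 lists. A gene below an FPKM of 1 in both other libraries was tested only if it reached 1 in both VE libraries. Of the extraembryonic ectoderm, parietal endoderm and primitive streak lists 4 of 16, 6 of 14 and 5 of 12 members were tested. For such lists an upward camera result can come from the filter, so it does not show that the list is higher in VE. Rps19 and Rplp1 were higher in VE by 1.35 ± 0.25 and 1.06 ± 0.19 and Rplp0 was lower by -2.35 ± 0.48, and after rescaling to a common sum Rps19 and Rplp1 were lower instead (-0.13 and -0.42, not passing). The distal and anterior visceral endoderm list had a median of 0.54 and a mean of -0.17. Of naive pluripotency the 1 member tested passed lower, and the lists for decidua, blood and stress had too few members to test. Fry, which does not compare a list with other genes, passed 8 lists, all lower in VE, and 0 of the 6 that passed camera. At E5.25, E5.5 and E5.75 it passed 10, 12 and 14 lists, of which 0, 1 and 2 downward, and 2, 7 and 6 were those that passed camera in the same direction.

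The labels also divide 8 of the E5.5 section numbers into parts A and B, with 16 samples. The E5.5 table held 1 value per section for 7 of these numbers, so the comparison of part A with part B was not run. Section 10 had separate values for its parts, without replicates, with 6387 genes detected in part A and 6467 in part B. The list of mitochondrially encoded genes had 0 of its 12 members in the tables.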

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

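The tests of detection on the E5.5 rises and on the E5.75 lists, of Lars2 against Rn45s and of the list centres were chosen only after the results were seen. In all, 50 measures, such as genes detected and list means, were checked over the sections of E5.25 or of E5.5 for a section far from the others. Of these, 3 had one, each time section 1 of E5.5. Chance gives about 1 in 20, so the count is near that share. The measures are related and all 3 point at the same section, so the share does not show that section to be ordinary. The 17 sections of E5.75 were not checked. In section 1 of E5.5 the summed FPKM was 571857, with 163101 in the nearest section. Gapdh was at 0 there, with 5.98 in the nearest section, and the mean of the FGF list was 0, with 1.12 in the nearest. The slope of the glycolysis list was lower at E5.75 than at E5.5 by a difference of -2.25, over 13 and 12 members, and that of the Nodal list lower at E5.75 than at E5.25 by -1.96, over 9 and 5 members. The glycolysis test was not repeated without section 1 of E5.5. Relative to the mean of all tested genes the Nodal difference did not pass (permutation p = 0.0117, adjusted p = 0.115).

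Most genes past the threshold at E5.5 rose with section number. With Rn45s and Lars2 removed and the rest rescaled, 1882 genes passed. Rescaling leaves genes listed at 0 unchanged, so this count does not decide whether the high share of Rn45s and Lars2 is a cause. Fewer genes detected in low-numbered sections remains a candidate explanation: the 28 ribosomal protein and glycolysis genes had a median change of 3.39, and with detected genes as a covariate 0 genes passed. Neither value decides it. The rise of the 28 genes is part of the pattern itself. Detection rose from 2288 genes in section 1 to 6387 and 6467 in parts A and B of section 10. The covariate thus largely follows section number and takes up much of any trend. A biological difference between sections stays open.

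At E5.75 the epiblast list fell while the ectoplacental cone list rose. Lower detection would move both lists alike, and with detected genes as a covariate the difference of their medians was 11.62, against 8.39 without it. RNA from decidua in high-numbered sections was set against the rise: with the decidua mean as a covariate the trophoblast list had a median change of 3.39 against 5.10, and 5 of the 11 members that had risen still passed. Sections 5 to 8 had 6923 to 7689 genes detected and sections 10 to 19 had 6916 to 8217. The mean of the epiblast list was 4.68 to 5.20 in the former and 1.36 to 2.60 in the latter. That of the ectoplacental cone list was 0.54 to 1.59 and 1.76 to 5.47. These values argue against lower detection as the cause, for these lists and sections. How much decidua RNA adds to the trophoblast rise is not settled. A difference in tissue along the axis would give both moves, but it was found and tested on the same sections of 1 embryo.

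Most genes past the threshold in the VE comparison were listed at 0 in both VE libraries. Few genes captured in these libraries is a candidate explanation that the test made does not decide. A median of 61.5% of these genes were also at 0 in sections 1 and 2 of E5.75, which have few genes too, against 50.6% of all genes tested and 39.3% of the tested genes outside this set. The bound of 50% set beforehand was thus met, but also by the tested genes as a whole. That comparison was added after the value was seen, and the label was changed from fits to cannot tell. Both low capture and a difference in cell type, which the VE label implies, stay open.

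The order of the sections was drawn anew for 100 orders per stage, the real one included. At E5.25, 5 orders gave at least as many genes as the real 29, with 707 in the highest other, so chance is not excluded. At E5.5 only 1 order, the real one, reached 2547, with 2112 in the highest other, and at E5.75 only 1, the real one, reached 2339, with 0 in the highest other. A random order of these sections thus rarely gave as many genes, and 1 of 100 is the smallest share this draw can give. The draw treats sections as exchangeable. It cannot tell a trend in expression from a trend in detection along the sections.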

How the results depend on the processing

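The fits without Rn45s and Lars2, those without sections of low detection, the list tests with detected genes as a covariate, the VE list test with quantile normalization and the relative slopes were chosen only after the data were seen. Causes were not tested unless stated.

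At E5.25, 29 genes passed. The count was 1006 with pseudocount 0.1, 877 with a filter at FPKM 5, 1144 after rescaling to a common sum, 514 with eBayes without trend and 79 with a spline. It was 0 in limma with pseudocount 5 (2258 at an unadjusted p under 0.05), no filter (2365), quantile normalization (1589), robust eBayes (2477), detected genes as a covariate (599) and without Rn45s and Lars2 (2542). Leaving out 1 section gave 3 to 818: 3 without section 6, 7 without section 7, 102 without section 8, 185 without section 2, 505 without section 3 and 818 without section 4. The 5 lists, 2 up and 3 down, became 0 with an estimated correlation and 3 with detected genes as a covariate, 2 up and 1 down, and were 4 up and 1 down with quantile normalization.

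At E5.5, 2547 became 1179 with quantile normalization, 0 with detected genes as a covariate (411 unadjusted) and 1115 without the first and last section; leaving out 1 section gave 1703 to 2584. The 10 lists, 6 up and 4 down, became 0 with an estimated correlation, 5 with quantile normalization, 4 up and 1 down, 3 with detected genes as a covariate and 6 without the section of low detection.

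At E5.75, 2339 became 1341 with quantile normalization, 624 with detected genes as a covariate, 3521 with a spline and 1407 without the sections of low detection; leaving out 1 section gave 1677 to 2487. The 8 lists became 3 with an estimated correlation. Of the calls, Nid2 was lost in 19 of 29 alternatives, Fzd5 in 15 of 29, Lhx1 in 12 of 28, Cited1 in 12 of 30 and Nodal in 7 of 30.

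In the VE comparison 3671 became 1688 with a filter at FPKM 5, 0 with quantile normalization (3090 unadjusted) and 1053 with detected genes as a covariate, 638 higher and 415 lower against 40 and 3631. Leaving out 1 library gave 2 to 5624: 2 without the other library of section 6 or of section 7, and 5624 without the VE library of section 7; the lone sample is then assumed to vary like the other group. With the section as replicate block 3800 genes and 6 lists passed. The 6 lists became 0 with an estimated correlation.

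Genes shared in direction by E5.25 and E5.5 went from 27 to 607 with a filter at FPKM 5 and 718 with pseudocount 0.1, and by E5.25 and E5.75 from 19 to 442 and 495. Of list slopes, 2 differed between stages and 1, that of glycolysis, relative to the mean of all tested genes; that of Nodal was lost.

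With detected genes as a covariate the sign reversed for Tdgf1 (1.64) and Pou3f1 (-1.37) at E5.25, for Lhx1 (0.0362), Apoe (-0.93), Rb1 (6.89), Hoxa10 (2.005), Epcam (-0.59), Gapdh (-3.19) and Ldha (-0.66) at E5.5, and in VE for Lrpap1 (-3.34), Rps19 (-0.88), Fst (-19.37), Lhx1 (-21.83), Krt18 (66.02), Eomes (-9.97) and Rn45s (-3.16), a fit of 4 libraries with 3 coefficients. Pou3f1 at E5.25 also reversed without sections of low detection (-0.28). After rescaling to a common sum Rplp1 (-0.42), Rps19 (-0.13) and Eomes (-0.33) reversed in VE, and Krt18 reversed with pseudocount 5 (0.0765) and without the VE library of section 6 (3.16, against -5.01 without that of section 7). Of the values of 57 genes named at E5.75, 1622 kept direction and side of the threshold, 79 no longer passed, 2 newly passed and 0 reversed. These counts were 273, 84 and 33 at E5.25, 780, 51 and 8 at E5.5, and 300, 92 and 8 in VE, beside the reversals above.

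Not run, for want of separate values for parts A and B: the comparison of part A with part B and its alternatives, the E5.5 trend over all 17 samples, with section as a factor, with part A alone and with part B alone. The fit over all 21 samples of E5.75 ran with 19 columns (3300 genes). Depth is unknown and sets no limit that can be computed.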

Other observations

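The tests of Lars2 against Rn45s and of the list centres were chosen only after the results were seen. Lars2, a mitochondrial leucyl-tRNA synthetase, was high where Rn45s was high. Across the 17 sections of E5.75 Pearson's r was 0.908 (permutation p = 2e-05, adjusted p = 3e-05 over 3 stages) and Spearman's rho 0.806 (permutation p = 0.00018, adjusted p = 0.00027), and r was 0.73 without the 2 sections farthest from the median. The Lars2 value may follow ribosomal RNA reads, and its falls are then not those of a gene.

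Trophoblast genes were centred at higher section numbers than extraembryonic ectoderm genes at E5.75. The median centre was section 14.6 against 12.7, a difference of 1.88 (permutation p = 0.047, 2-sided, 14 and 16 genes, which are not independent replicates). In a spline fit 12 trophoblast genes passed and all peaked above section 12, while of 14 extraembryonic ectoderm genes 6 peaked in sections 10 to 12 and 8 above. This may reflect an order of the tissues along the axis of this embryo.

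Several genes with large rises at E5.75 are imprinted, and a list of 43 imprinted genes was tested for a joint rise. Of 29 tested, 9 rose and 0 fell (10 adjusted over the list alone, median 1.04), and camera gave p = 0.083 at the preset correlation and 0.141 with an estimated correlation, so the list did not pass as a whole. With detected genes as a covariate it gave p = 0.0253 at the preset correlation. The test was made because some imprinted genes had been seen to rise, and those genes are in the list.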
